A study of Mus musculus with 24 samples.

How the data were processed

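RNA-seq was analysed for 24 libraries of mouse lung adenocarcinoma cells, in 6 groups of 4. Per the labels' protocols, total RNA was taken with Trizol from cultured tumour cells, libraries were made by the TruSeq Stranded Total RNA protocol and sequenced on an Illumina NovaSeq, and the molecule is named as polyA RNA. The authors deposited whole-number counts per gene, not normalised, as a table of 8 libraries for the shRNA samples and a table of 16 libraries for the siRNA samples. Per the submitters' processing notes the genome build was mm10 and DESeq2 1.24.0 was used. The aligner, the counting program, its strand setting and the annotation are not given in the sources used here, so genes that share reads with a near-identical copy, or that overlap another gene, are uncertain. Each column matched 1 sample by name, and the columns without a sample numbered 0. All 38937 gene symbols of the shRNA table and all 39310 of the siRNA table were found in the reference annotation of GRCm38.p6, the assembly that mm10 names, from which coordinates are given counting from 1. No count was recorded in any library for 9421 and 3763 of these genes.

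Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups, which left 14697 genes in the shRNA table and 18138 in the siRNA table. Library sizes were scaled by TMM, and the quasi-likelihood test with robust estimation was applied to each comparison. Benjamini-Hochberg adjustment ran over all genes tested, and genes with an adjusted p under 0.05 are said to have risen or fallen. The 8 shRNA libraries were fitted by themselves, and the 16 siRNA libraries in a model with 1 term per group that shared 1 estimate of the spread. The comparisons were shAtf4 against shControl in S/S cells, siChchd10 against siControl in S/S cells and in A/A cells, the difference between those siChchd10 effects (the interaction, A/A minus S/S), and A/A against S/S cells that had both received siControl. Expression levels are counts per 1e6 counts (CPM) after TMM scaling, given as mean ± SD over 4 libraries. Fold changes are on the log2 scale with their standard errors (SE). The labels do not say whether the 4 libraries of a group came from separate cultures, so every p-value measures only the spread between these samples.

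The 35 gene lists, the comparisons, the tests, the rule for naming genes and the alternatives were chosen before the data were examined, apart from the alternatives and tests that the closing section names as added later. The lists cover ATF4-linked amino acid genes, ATF4-linked stress genes, cytosolic tRNA synthetases, and chaperones and stress genes of the endoplasmic reticulum. They also cover nuclear respiratory chain subunits, mRNAs of mitochondrial DNA, mitochondrial and cytosolic ribosomal proteins, cristae proteins and mitochondrial chaperones and proteases. Further lists hold markers of alveolar type 2, alveolar type 1, transitional alveolar, gut endoderm, airway, basal and neuroendocrine cells, epithelial junction and mesenchymal genes, and S phase and G2/M genes. The rest cover cholesterol synthesis, fatty acid synthesis and oxidation, NRF2 targets, glycolysis and hypoxia, the interferon response, NF-kB targets, p53 targets, MHC class I genes, autophagy and lysosome genes, non-polyadenylated RNAs as a mark of RNA quality, and markers of leukocytes, fibroblasts and endothelial cells. Each list was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes. This two-sided test asks whether the members of a list moved one way relative to all other genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts of list members that rose or fell use the adjustment over all genes, and the count adjusted over the list alone stands beside a given count where it differs from it.

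Genes were named by rule. In each comparison of 2 groups, the rule took genes past the threshold with an average log2 CPM of 1 or more whose 4 libraries in one group all lay above the 4 of the other. From these it named the 10 largest rises and the 10 largest falls, without predicted genes, clone names and pseudogenes. The interaction used the same rule without the condition on separate libraries. For each list the rule named up to 2 members with the largest rise and 2 with the largest fall among those past the threshold, or the 2 smallest p-values where none passed. Some of the genes that the rule gave are not reported here. The targets Atf4 and Chchd10, and Eif2s1, which encodes eIF2α, were always named. Sftpc, Hnf4a, Nkx2-1 and Cdkn2a, the Y-linked genes and Xist, and the RNAs used to trace mixing between cultures were picked after their values were seen, except where the rule also gave them.

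The labels number the libraries of each group from 1 to 4 without saying that a number marks a shared culture or day. The correlation of deviations from the group means was therefore checked over all genes tested, and a value above 0.1 in every pair was taken to mean that the numbers pair the libraries. In the shRNA table, libraries with the same number correlated at 0.450, 0.403, 0.241 and 0.789, so by this rule the numbers were taken to pair them. Among replicates 1 to 3, libraries with unlike numbers also passed 0.1 (0.121 to 0.314). The rule therefore does not establish the pairing for these replicates. S/S shControl replicate 3 correlated best with S/S shAtf4 replicate 2, at 0.314. A fit with the replicate number as a block is given beside the counts, the named genes and the lists called in that table where it changed a call. In the siRNA table the numbers did not meet the rule.

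A fold against a group with no count in any library is a lower bound, computed against a floor of 3 counts per library. Such bounds and the intervals of count ratios cover counting error only. The alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, other size factors, other filters on low counts (none, or a CPM of at least 1 in at least 4 libraries), a test against a minimum fold of 1.5, the replicate block, the compared groups fitted alone, and leaving out each library in turn. For the lists they were an estimated correlation between genes, ranking by the edgeR statistic, the block and the stricter filter.

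The procedure was tested on simulated data made from the real means and library sizes, with 200 genes changed by 1.5-fold, 2-fold or 4-fold. Before that change each gene had the same mean in all groups. The changed genes and the lists were drawn from genes with a mean of at least 20 counts. The recoveries therefore do not cover genes near 0 in a group. For shAtf4 against shControl, over 14436 genes, it recovered 5.97% of genes changed 1.5-fold, 59.7% at 2-fold and 86.4% at 4-fold, with 10 false calls among 111. For siChchd10 in S/S cells (17699 genes) it recovered 86.6%, 95.5% and 100%, with 11 false calls among 199. For siChchd10 in A/A cells (17710 genes) the shares were 82.1%, 94.0% and 98.5%, with 9 false calls among 192. For the interaction (17706 genes) they were 67.2%, 79.1% and 100%, with 7 among 171, and for A/A against S/S (17683 genes) 74.6%, 91.0% and 100%, with 6 among 183. In each comparison 10 of 10 simulated lists that had been raised were called, and 0 of 200 random lists. The simulation was made from means and library sizes, without the real correlation between genes. It therefore cannot decide whether the preset correlation is adequate for the real lists. An estimated correlation kept 2 of the 20 list calls for siChchd10 in S/S cells and 0 in every other comparison. Only 200 genes were changed, against 5076 to 12741 past the threshold in the siRNA comparisons.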

Results

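RNA was sequenced from 24 libraries of cultured mouse lung adenocarcinoma cells that had been sorted as GFP-positive and CD45-negative tumour cells. eIF2α is a translation initiation factor, and phosphorylation of a serine in it starts the integrated stress response. The S/S cells carried the wild-type form, and the A/A cells a form with alanine at that serine, which cannot be phosphorylated. The libraries fell into 6 groups of 4. In one table of 8 libraries, S/S cells carried a control shRNA (S/S shControl) or an shRNA against Atf4 (S/S shAtf4). In another table of 16 libraries, S/S and A/A cells had received a control siRNA or an siRNA against Chchd10 (S/S siControl, S/S siChchd10, A/A siControl and A/A siChchd10). ATF4 is the transcription factor that is translated when eIF2α is phosphorylated, and CHCHD10 is a protein of the mitochondrial intermembrane space. The comparisons ask how ATF4, CHCHD10 and the phosphorylation site bear on mitochondrial genes and on lineage genes in these tumour cells.

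Total counts, in units of 1e6, were 70.9, 64.0, 26.6 and 17.5 for replicates 1 to 4 of S/S shControl and 14.1, 17.5, 23.4 and 59.9 for S/S shAtf4. The totals were 42.9, 53.03, 52.0 and 48.2 for S/S siControl and 47.5, 49.8, 51.9 and 48.9 for S/S siChchd10. In the A/A cells they were 51.9, 50.03, 48.6 and 46.0 with siControl and 49.5, 52.8, 47.5 and 75.4 with siChchd10. In the shRNA table the first principal component of the 1000 most variable genes held 46.9% of the variance and set replicate 4 of each group (46.0 in shControl and 36.1 in shAtf4) apart from the other libraries (-20.6 to -5.48). The second component, with 31.3%, separated shAtf4 from shControl. The replicate 4 libraries also had a lower median of the interferon list than replicates 1 to 3, by a log2 difference of -2.78 in shControl and -2.37 in shAtf4, and a higher median of the non-polyadenylated RNAs, by 0.71 and 0.66. In the siRNA table the first component held 92.9% of the variance and separated S/S (-69.3 to -63.1) from A/A libraries. A/A siControl replicate 1 lay nearest to the S/S side, at 36.6, against 59.2, 66.9 and 66.1 in replicates 2 to 4. RNAs of 7 genes that were abundant in all S/S libraries and nearly absent from all A/A siChchd10 libraries stood in that library at 6.48% of their S/S siControl level, against 0.990% in replicate 2. The second component, with 3.33%, separated siChchd10 from siControl within each genotype.

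**Figure D1:**
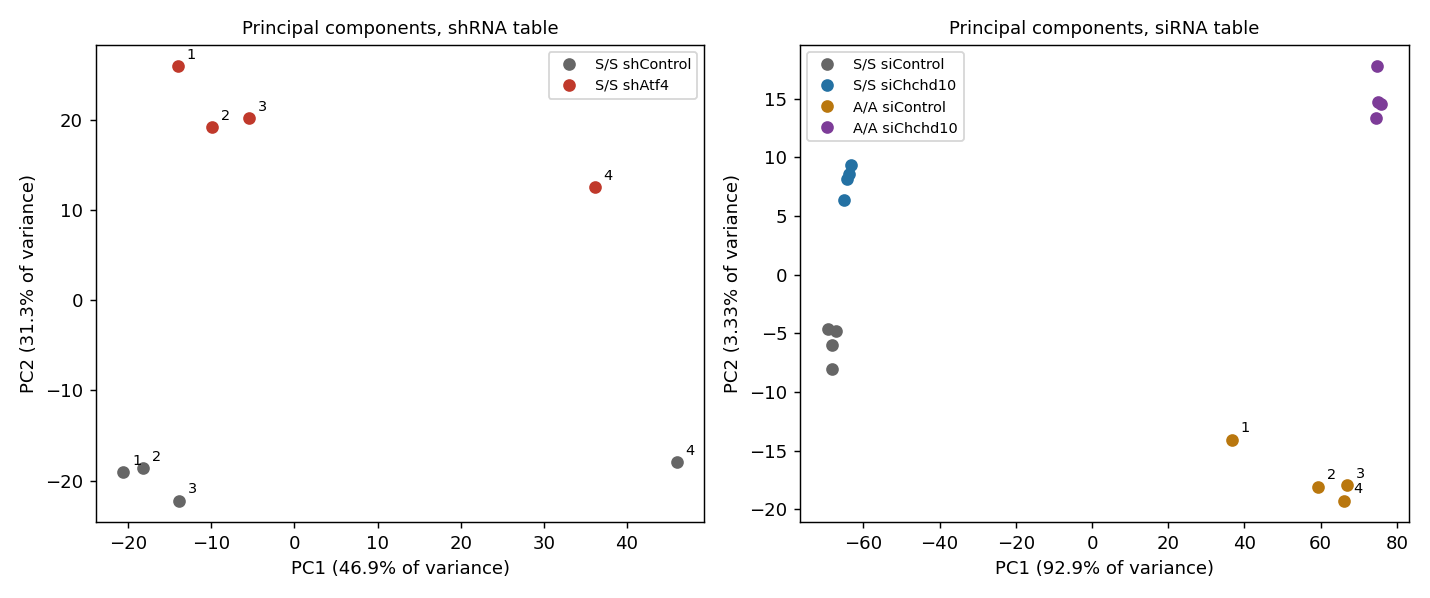
Scores of each library on the first and second principal components of log2 CPM (arbitrary units), for the shRNA table and the siRNA table; each point is a library and colour gives its group. Replicate 4 of both shRNA groups lies apart on the first component (46.0 and 36.1), and A/A siControl replicate 1 lies at 36.6.

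The targeted genes were examined in every library before anything else. Atf4 (chromosome 15, 80255184 to 80257545, GRCm38.p6) measured 565, 835, 818 and 498 CPM in S/S shControl replicates 1 to 4 and 302, 237, 319 and 225 CPM in S/S shAtf4, so all 4 knockdown libraries lay below all 4 controls. It fell by 1.33 on the log2 scale (SE 0.197, adjusted p = 0.0327 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), to 39.9% of the control level. Leaving out any library other than S/S shControl replicate 4 ended that call, with adjusted p from 0.0655 (without S/S shControl 1) and 0.0658 (without S/S shAtf4 4) to 0.131 (without S/S shControl 3). With the replicate block Atf4 fell by 1.31 (adjusted p = 0.00431). Chchd10 (chromosome 10, 75933130 to 75937750) measured 40.6, 45.5, 38.1 and 46.0 CPM in S/S siControl and 6.69, 5.34, 6.33 and 6.82 CPM in S/S siChchd10. In A/A cells it measured 10.2, 9.53, 7.97 and 7.99 CPM with siControl and 1.37, 1.75, 2.04 and 2.15 CPM with siChchd10. The siRNA left 14.8% of the Chchd10 level in S/S cells (log2 fold change -2.76, SE 0.0963, adjusted p = 5.12e-16) and 20.7% in A/A cells (-2.27, SE 0.121, adjusted p = 2.26e-13). Without siRNA against it, Chchd10 in A/A cells stood at 21.0% of its S/S level (-2.25, adjusted p = 1.77e-16). After shAtf4 it stood at 46.2% of control (-1.11, adjusted p = 0.176), which did not pass the threshold, and with the block it fell by 1.05 (adjusted p = 0.00192). Atf4 mRNA in A/A siControl was 31.7% of the S/S level (-1.66, SE 0.0566, adjusted p = 1.73e-19). After siChchd10 Atf4 fell by 0.21 in S/S (adjusted p = 0.00495) and by 0.38 in A/A cells (adjusted p = 2.51e-06), and the difference between the effects did not pass (adjusted p = 0.0932). Eif2s1 (chromosome 12, 78862072 to 78887010), which encodes eIF2α, did not pass after shAtf4 (0.15, adjusted p = 0.884), and it fell by 0.14 in A/A against S/S cells (adjusted p = 0.00690).

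**Figure D2:**
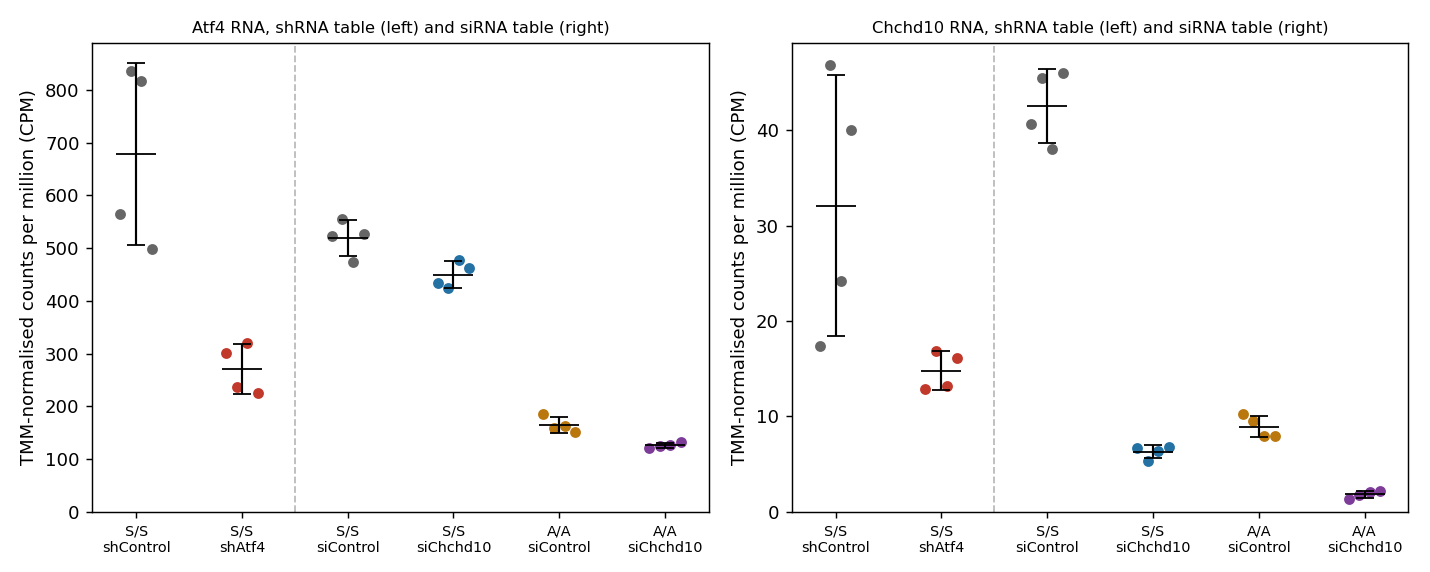
Atf4 (left) and Chchd10 (right) in TMM-scaled CPM in each of the 24 libraries; points are libraries, and bars give the mean and SD of 4 libraries. Chchd10 lies between 38.1 and 46.0 CPM in S/S siControl and between 7.97 and 10.2 CPM in A/A siControl.

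Knockdown of Atf4 in S/S cells asks which genes depend on this factor when eIF2α can be phosphorylated. Of 14697 genes tested, 79 passed (0.538%): 22 rose and 57 fell, and 61 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 1549. With the replicate block 2969 genes passed, 1487 higher and 1482 lower, including 78 of the 79. Leaving out a single library gave between 13 (without S/S shAtf4 2) and 536 genes (without S/S shControl 4). Among the falls was Stc2, which encodes the secreted glycoprotein stanniocalcin 2 and is induced by ATF4. It had no count in any shAtf4 library and was at least 29.4-fold lower than in shControl (4.14 CPM). Aldh1l2, a mitochondrial enzyme of folate metabolism and another ATF4 target, fell from 88.5 ± 58.8 to 12.8 ± 3.51 CPM (-2.80, adjusted p = 0.0358). Wnt5a, a ligand of non-canonical Wnt signalling, fell from 29.7 ± 6.71 to 3.57 ± 1.21 CPM (-3.08, adjusted p = 0.00253), and Gas6, the ligand of the receptor AXL, fell by 2.76. The collagen receptor gene Ddr2 (-4.99, and -4.37 without S/S shControl 2) and the kainate receptor partner Neto2 (-3.99) also fell. Another 4 of the 10 named falls were the Y-linked genes Uty (-5.66), Ddx3y (-5.58), Kdm5d (-5.48) and Eif2s3y (-5.01), and Ddx3y went from 48.4 ± 3.85 to 0.979 ± 0.320 CPM. A different cell population in the shAtf4 libraries stays open as a source of the Y-linked falls. The changes in this comparison therefore cannot be told apart from differences between cell populations. Among rises, Ebf3, a developmental transcription factor, went from 0.297 to 12.3 CPM (5.08, adjusted p = 0.0417). Of its 74 shControl counts 68 lay in S/S shControl 2 (1.06 CPM, the other 3 libraries at 0 to 0.0733), so the fold rests on that library. Without it the control level is under the floor of 3 counts per library and the call stayed. The adhesion gene Nectin3 (2.53) and Ctnnd2 (2.18), a catenin, rose. Dmd (1.82) and the glycosyltransferase gene B4galnt3 (1.74) followed. Tenascin C (Tnc, 1.56) went from 89.5 to 263 CPM and the keratin gene Krt7 (1.49) from 251 to 704 CPM, while Greb1l (1.12) and the chemokine gene Ccl9 (1.06) rose less. Nectin3, Wnt5a, Gas6 and the 4 Y-linked genes kept their calls when any single library was left out. The other 13 of the 20 genes that the naming rule gave each lost theirs without at least 1 library other than S/S shControl 4 (adjusted p 0.0509 to 0.190), and 0 of the 20 lost it with the block.

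In the gene lists for shAtf4, few members passed singly, while camera called 13 of 33 lists. With an estimated correlation between genes none of the 13 held, and their adjusted p-values then ranged from 0.544 to 0.734. Of the 25 ATF4-linked amino acid genes, 1 fell (Aldh1l2), 24 did not pass, and 3 fell when adjusted over the list alone. The list median was -0.38 (camera adjusted p = 1.67e-06, and adjusted p = 0.663 with an estimated correlation), and with the block 19 of the 25 fell and none rose. Of 19 ATF4-linked stress genes, 1 fell (Stc2), 5 did when adjusted over the list alone, and 14 did with the block (median -0.49, camera adjusted p = 4.47e-05, adjusted p = 0.663 with an estimated correlation). The interferon list had 0 of 27 members past the threshold and a median of 0.70 (camera adjusted p = 0.000130, adjusted p = 0.709 with an estimated correlation). With the block 19 of the 27 rose, among them the sensor Zbp1 (1.76 without the block) and Oasl1 (0.77). MHC class I genes gave 0 of 14, and 12 higher with the block, Psmb10 among them (list median 0.37, camera adjusted p = 0.00235, adjusted p = 0.663 with an estimated correlation). Mitochondrial ribosomal proteins gave 0 of 78, and 17 higher with the block, Mrps2 among them (list median 0.15, camera adjusted p = 1.67e-06, adjusted p = 0.663 with an estimated correlation). S phase genes (0 of 26, 6 higher with the block) and cristae genes (0 of 20, 8 higher with the block) were called higher, and mRNAs of mitochondrial DNA (0 of 13, 5 lower with the block, median -0.25) lower, each with adjusted p = 0.663 with an estimated correlation. Cytosolic ribosomal proteins (0 of 85, 8 higher with the block, median 0.03) and the respiratory chain list (1 of 74 rose, Ndufs3, 0.54, and with the block 7 rose and 1 fell) were called higher, with adjusted p = 0.734 with an estimated correlation. The airway list had 4 tested members, 0 passed, 2 fell when adjusted over the list alone and 3 fell with the block, the mucin gene Muc5b (-3.31) among them (camera adjusted p = 0.00481, adjusted p = 0.544 with an estimated correlation). Autophagy and lysosome genes (0 of 28, 7 lower with the block) were called lower, with adjusted p = 0.663 with an estimated correlation. So were NF-kB targets (1 of 24 fell, Saa3, an acute phase gene, -3.45, and 5 adjusted over the list alone), a call that ended with the block (adjusted p = 0.0587), where 1 rose and 6 fell. The block added calls for transitional alveolar genes, higher (adjusted p = 0.0349, 6 higher and 2 lower of 24, adjusted p = 0.7195 with an estimated correlation), and for fatty acid oxidation, lower (adjusted p = 0.0349, 1 higher and 4 lower of 18, adjusted p = 0.7172 with an estimated correlation). Krt7 rose and Ndrg1 fell as the transitional genes past the threshold without the block (3 higher and 2 lower adjusted over the list alone), and no fatty acid oxidation gene passed (1 lower adjusted over the list alone). Without the block Ndrg1 fell by 1.08 (adjusted p = 0.0411), and with it Ndrg1 did not pass (0.0556). Cdh1, which encodes E-cadherin, fell by 0.67 as the only epithelial junction gene of 21 past the threshold (1 higher and 3 lower adjusted over the list alone), and with the block 6 of the 21 rose and 4 fell; that list was not called (camera adjusted p = 0.325). Hnf4a, a factor of gut and liver lineages, lay at -1.93 (adjusted p = 0.0618), and fell with the block (4.23e-05), where 1 gut endoderm gene rose and 4 fell of 8; without the block none of the 8 passed (2 lower adjusted over the list alone). For cholesterol synthesis the median was -0.09 and the test direction higher (camera adjusted p = 0.838). For chaperones and stress genes of the endoplasmic reticulum the median was 0.01 and the direction lower (camera adjusted p = 0.325). Fibroblast markers (4 tested) had a median of -0.21 and the test direction higher (0.918). The replicate 4 libraries lay apart in the interferon genes, as described for the first component, and in the cholesterol genes, as given in the closing observations. This spread entered the tests without the block.

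Knockdown of Chchd10 in S/S cells asks what loss of this mitochondrial protein does while eIF2α can be phosphorylated. Effects of this siRNA apart from Chchd10 cannot be told apart from the knockdown, here or in A/A cells. Of 18138 genes tested 5076 passed (28.0%), 2720 higher and 2356 lower, and 598 changed at least 2-fold (388 higher, 210 lower). Against a minimum fold of 1.5, 381 passed. Several of the named falls were of genes that interferon induces. The antiviral synthetase gene Oas3 fell from 11.5 ± 3.44 to 1.85 ± 0.430 CPM (-2.65, SE 0.213, adjusted p = 5.31e-08), and Xaf1 (-2.22), Ifit3 (10.03 to 2.51 CPM), Rsad2 (-1.82), Cmpk2 (-1.81), Ifit3b (-1.81) and Ifit1 (-1.81, 26.8 to 7.65 CPM) fell with it. Apol9a (15.7 to 3.94 CPM) and Apol9b (-1.95), a pair of near-identical neighbours that can share reads, fell too. Lama3, a chain of an epithelial laminin, went from 1.76 ± 0.229 to 14.6 ± 0.575 CPM (3.05, adjusted p = 1.54e-16), and the intestinal surface antigen gene Gpa33 from 2.24 to 14.4 CPM (2.69). Eps8l3 (3.28), the mucin gene Muc4 (2.89), the receptor gene Gpr55 (2.82), and the genes for kininogen 2 (Kng2, 2.55) and prothrombin (F2, 2.53) rose, each from under 1 CPM. Sprr2a3 (2.48), one of a family of similar cornified envelope genes, rose too. Ptprn2 had 12 counts against 1, a ratio of 11.9 (counting interval 1.76 to 509), and its call ended without S/S siControl 2, 3 or 4 or S/S siChchd10 4 (adjusted p 0.0647 to 0.0801). Lelp1 had 55 counts against 9, a ratio of 6.06 (2.97 to 13.9).

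Among the lists for siChchd10 in S/S cells, camera called 20 of 35, and 2 of these held with an estimated correlation. Of 26 interferon genes, 25 fell, among them Oas1a (-2.36) and Xaf1, and 1 rose (median -1.38, camera adjusted p = 1.32e-26, adjusted p = 0.00297 with an estimated correlation). Of 25 epithelial junction genes 19 rose, 20 when adjusted over the list alone, and none fell. The membrane protease gene St14 rose by 2.21 and the adhesion gene Epcam by 1.96, from 8.93 to 34.8 CPM (list median 0.53, camera adjusted p = 7.84e-11, adjusted p = 0.0162 with an estimated correlation). The next lists were called with the preset correlation only. Of 25 ATF4-linked amino acid genes 18 fell and none rose, among them Bcat1 (-0.97) and Cth (-0.65), which serve branched-chain amino acid breakdown and cysteine synthesis (median -0.28, camera adjusted p = 6.44e-11, adjusted p = 0.163 with an estimated correlation). ATF4-linked stress genes gave 11 falls (12 adjusted over the list alone), Gdf15 (-0.53) and Nupr1 (-0.50) among them, and 1 rise of 19, and cytosolic tRNA synthetases 14 falls of 20, with Nars (-0.37) and Lars (-0.36), both with adjusted p = 0.380 with an estimated correlation. Mesenchymal genes gave 15 falls, with Prrx1 (-1.08) and Tgfb2 (-0.94), and 3 rises of 21 (camera adjusted p = 3.71e-06, adjusted p = 0.0636 with an estimated correlation). Gut endoderm genes gave 11 rises of 18, with Lgals4 (2.13), which encodes an intestinal galectin (22.4 to 97.7 CPM; camera adjusted p = 3.71e-06, adjusted p = 0.186 with an estimated correlation). Transitional alveolar genes gave 15 rises, with Slc4a11 (1.15) and Cldn4 (1.10), and 3 falls of 24 (adjusted p = 0.259 with an estimated correlation). Alveolar type 2 genes gave 7 rises, with Sftpb (1.67) and Muc1 (1.37), and 1 fall of 16, and alveolar type 1 genes 6 falls, with Cav1 (-0.84), and 1 rise of 17 (6 and 2 adjusted over the list alone), both with adjusted p = 0.380 with an estimated correlation. Fatty acid synthesis (9 rises of 15, 11 adjusted over the list alone, with Fasn, 0.53, and Mlxipl, 0.67) had adjusted p = 0.380 with an estimated correlation. Cholesterol synthesis (13 rises and 2 falls of 25, 16 and 2 adjusted over the list alone) had adjusted p = 0.509 with an estimated correlation. Glycolysis and hypoxia genes (12 rises and 2 falls of 28, 15 and 3 adjusted over the list alone) had adjusted p = 0.655 with an estimated correlation. Targets of p53 (7 rises of 18, Perp by 0.70 and Cdkn1a by 0.56) and airway genes (3 rises of 7, Aldh1a1 by 0.98) both had adjusted p = 0.341 with an estimated correlation. NF-kB targets (8 rises and 2 falls of 22) had adjusted p = 0.380 with an estimated correlation. The respiratory chain list had 1 rise and 5 falls of 74 (1 and 2 adjusted over the list alone), mitochondrial ribosomal proteins 1 and 10 of 78 (0 and 5 adjusted over the list alone), and cytosolic ribosomal proteins 0 and 10 of 85, each called lower with adjusted p = 0.8288 with an estimated correlation, and mitochondrial chaperones and proteases 0 and 3 of 15, Hspa9 (-0.35) among them (adjusted p = 0.655 with an estimated correlation). The mRNAs of mitochondrial DNA had 3 rises and no falls of 13 (2 and 0 adjusted over the list alone, median 0.16) and were not called. Ranking by the edgeR statistic ended the calls of the respiratory chain (adjusted p = 0.0581), mitochondrial ribosomal proteins (0.102), mitochondrial chaperones and proteases (0.0513) and NF-kB targets (0.0515), and the stricter filter those of alveolar type 1 (0.0940) and airway genes (0.1005). Median and mean differed in sign from each other for non-polyadenylated RNAs (-0.01 and 0.05), NRF2 targets (-0.00 and 0.01) and leukocyte markers (0.05 and -0.28). Neuroendocrine markers had a median of 0.02 and the test direction lower, and none of the 4 lists was called.

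The same knockdown in A/A cells asks what happens when phosphorylation of eIF2α cannot follow. Here 9748 of 18138 genes passed (53.7%), 4806 higher and 4942 lower, and 1603 changed at least 2-fold, 638 higher and 965 lower. Against a minimum fold of 1.5, 1425 passed. A/A siControl replicate 1 held RNAs of S/S type, which can add falls here. Without A/A siControl 1 and 2, 8317 genes passed, 4286 higher and 4031 lower. The gene lists were not tested without them. Sftpa1, which encodes surfactant protein A, went from 0.672 ± 0.0413 to 20.1 ± 3.02 CPM (4.90, SE 0.143, adjusted p = 2.63e-20), and Serpind1, a thrombin inhibitor, from 7.38 to 86.8 CPM (adjusted p = 2.63e-20). Kng2 (6.70) went from 0.0672 to 7.07 CPM. Its siControl level lay close to the floor of 3 counts per library (0.0604 CPM) and was highest in replicate 4 (0.150 CPM). The size of its fold is therefore imprecise, and it was 6.05 without A/A siControl 1 and 2. The mucin gene Muc4 (4.04), the fibrinogen chain gene Fga (3.94), the cytochrome gene Cyp2c55 (3.89), Ptprn2 (4.17), the histidine decarboxylase gene Hdc (3.58) and the protease gene Prss8 (3.44) rose from under 1 CPM. Among falls, the quinone reductase gene Nqo1 went from 16.2 ± 1.11 to 3.18 ± 0.577 CPM (-2.33, adjusted p = 1.46e-14), and Trim40 (-2.32), Nlrc5 (-2.18), a regulator of MHC class I genes, and Layn (-2.48) also fell. Trpv4 (-3.30), Sgsm1 (-2.51), Basp1 (-2.29), Acsl6 (-2.20) and Sox5, with 4 against 26 counts, a ratio of 7.30 (counting interval 2.53 to 28.8), fell as well, and all 5 were highest in A/A siControl replicate 1. The call of Sgsm1 ended with the replicate block (adjusted p = 0.0535). Basp1 measured 26.3 CPM in that library and 5.005 to 6.70 CPM in replicates 2 to 4, and it fell by 1.34 without replicate 1 and by 1.23 without replicates 1 and 2. Sgsm1 did not pass without them (-0.60, adjusted p = 0.232), nor without A/A siChchd10 3 (0.0509) or 4 (0.0766).

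Camera called 16 of 35 lists for siChchd10 in A/A cells, and none held with an estimated correlation (adjusted p 0.177 to 0.713). Of 74 nuclear respiratory chain genes 63 rose, 65 adjusted over the list alone, and none fell, with Ndufb10 and Ndufa5, subunits of complex I, both up by 0.55 (median 0.25, camera adjusted p = 1.03e-10, adjusted p = 0.712 with an estimated correlation). Mitochondrial ribosomal proteins gave 55 rises (57 adjusted over the list alone), Mrpl20 (0.53) among them, and 4 falls of 78, cristae genes 14 rises and 2 falls of 20 (14 and 3 adjusted over the list alone), and S phase genes 20 and 2 of 26, each with adjusted p = 0.712 with an estimated correlation. Fatty acid oxidation gave 15 rises of 19, with Etfb (0.60; adjusted p = 0.5004 with an estimated correlation), and mitochondrial chaperones and proteases 11 rises and 2 falls of 15 (adjusted p = 0.713 with an estimated correlation), a call that ranking by the edgeR statistic ended (0.0663). Chaperones and stress genes of the endoplasmic reticulum gave 19 rises of 22, with Pdia3 and Dnajb9 (both 0.44), and adjusted p = 0.370 with an estimated correlation. Alveolar type 2 genes gave 14 rises and 1 fall of 16 (median 0.85, camera adjusted p = 2.43e-06, adjusted p = 0.177 with an estimated correlation). Sftpc, the surfactant gene that marks this cell type, had 172 to 270 counts per library after siChchd10 and 3 to 5 before (5.35), and Sftpb went from 290 to 1177 CPM. Gut endoderm genes gave 12 rises, with Gkn2 (4.56) and Cym (2.99), and 2 falls of 18, and epithelial junction genes 13 rises, with Prss8 and Spint1 (2.13), and 2 falls of 25, both with adjusted p = 0.370 with an estimated correlation. Autophagy and lysosome genes gave 17 rises, with Hexa (0.91) and Lamp1 (0.66), and 3 falls of 28 (adjusted p = 0.462 with an estimated correlation). Mesenchymal genes gave 16 falls, with Tgfb2 (-1.47) and Itga5 (-1.24), and 2 rises of 21 (median -0.78, adjusted p = 0.177 with an estimated correlation). Glycolysis and hypoxia genes gave 20 falls and 1 rise of 28, with Adm (-2.02) and the lactate transporter gene Slc16a3 (-1.50, 73.5 to 26.1 CPM; adjusted p = 0.574 with an estimated correlation). Interferon genes gave 18 falls, with Oas1a (-1.98) and Rsad2 (-1.26), and 3 rises of 26 (camera adjusted p = 3.87e-05, adjusted p = 0.370 with an estimated correlation). Cytosolic tRNA synthetases gave 11 rises, with Wars (0.91), and 3 falls of 20, and cholesterol synthesis 11 falls and 4 rises of 25, both with adjusted p = 0.713 with an estimated correlation. The ATF4-linked lists were not called: 10 amino acid genes fell, with Slc7a11 (-0.98), and 4 rose of 25, and 7 stress genes fell and 3 rose of 19 (camera adjusted p = 0.350 for both). NRF2 targets (12 falls and 5 rises of 22), G2/M genes (10 and 1 of 25) and alveolar type 1 genes (7, with Cav1, -1.60, and 2 of 17) were not called either. The medians of MHC class I genes (-0.08), neuroendocrine markers (-0.06) and leukocyte markers (-0.31) were negative while the test pointed higher, without a call (camera adjusted p = 0.673, 0.673 and 0.997), and the endothelial markers had a median of -0.11 and a mean of 0.15.

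The difference between the siChchd10 effects, A/A minus S/S, passed in 6461 of 18138 genes (35.6%), 3026 higher and 3435 lower, with 1102 at least 2-fold. Against a minimum fold of 1.5, 600 passed. The labels do not say how many tumours the cells of each genotype came from. A differing response of the cell populations therefore cannot be told apart from the effect of the phosphorylation site. Of the 6461 genes, 666 changed in opposite directions in the genotypes (396 rose in S/S and fell in A/A cells, 270 the reverse), 950 changed in the same direction, 3816 passed in A/A cells only, 828 in S/S cells only and 201 in neither. Chchd10 itself fell less in A/A than in S/S cells (0.49, SE 0.161, adjusted p = 0.0205), starting from 21.0% of the S/S level. The 10 positive differences named by the rule kept their calls without A/A siControl replicates 1 and 2. Among them were Sftpa1 (4.46), Hdc (4.39), Kng2 (4.15), Cltrn, a partner in amino acid transport, Shisa6, Cyp2c55 (3.43), the metalloproteinase inhibitor gene Timp3 (3.38), Fga (2.71) and Aox3 (2.62). The difference for Kng2 rests on an A/A siControl level close to the floor, and was 3.50 without A/A siControl replicates 1 and 2. Cltrn rose in A/A cells from 35.2 to 81.1 CPM and had 12 counts over 4 libraries before and 2 after siChchd10 in S/S cells, at or under the floor of 3 counts per library, so no fold is given for the difference (adjusted p = 0.00168). Shisa6 fell in A/A cells from 9.03 to 4.70 CPM and lay under the floor in S/S cells, so it has no fold for the difference either (adjusted p = 0.0494). That call ended without S/S siControl 1 or 2, any S/S siChchd10 library, A/A siControl 3, or A/A siChchd10 2, 3 or 4 (0.0529 to 0.137), with limma-voom (0.291) and with upper-quartile factors (0.0541). The 10 negative differences named by the rule were of genes at or under 0.741 CPM on average in A/A siControl, with most of that in replicate 1, among them Hdx, Serpine2, Pax3, Esrp1, Slc9a2, Sntb1, Egflam, Stk26 and Tnik. In A/A cells after siChchd10 Hdx, Pax3 and Slc9a2 had no count, at least 3.45-fold, 1.97-fold and 1.37-fold less than before, and Esrp1 had none against 11 counts, under the floor in both. Counts were 2 against 156 for Serpine2, a ratio of 87.6 (counting interval 23.9 to 730), and 1 against 15 for Tnik, a ratio of 16.9 (2.59 to 709). The calls of Hdx and Serpine2 each ended without most single libraries (0.0532 to 0.116), those of Esrp1, Egflam and Tnik without A/A siControl 1, that of Tnik also without A/A siChchd10 1, 2 or 4 (0.0707 to 0.0924), and that of Stk26 without any A/A siChchd10 library (0.0518 to 0.0833). Without A/A siControl 1 and 2, only Hdx (adjusted p = 0.0221) and Stk26 (adjusted p = 0.00971) kept theirs. With limma-voom 5 of the 20 calls ended, Shisa6 and 4 negative differences, among them Serpine2 (adjusted p = 0.127), Esrp1 (0.0715) and Tnik (0.162). With the replicate block 7 of the 10 negative calls ended, among them Hdx (0.109), Serpine2 (0.0931), Pax3 (0.0669), Esrp1 (0.0674), Stk26 (0.0556) and Tnik (0.0777).

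In the lists for this difference camera called 19 of 35, none with an estimated correlation (adjusted p 0.321 to 0.417). Of 74 respiratory chain genes 67 were higher, 70 adjusted over the list alone, and none lower, with Ndufa5 (0.61) and Ndufa1 (0.47; camera adjusted p = 4.09e-15, adjusted p = 0.417 with an estimated correlation). The same estimated value, adjusted p = 0.417 with an estimated correlation, held for every other list of this paragraph that was called except the interferon list. Higher were mitochondrial ribosomal proteins (50 against 1 lower of 78, 54 and 2 adjusted over the list alone, Mrpl40 by 0.51), cristae genes (12 of 20), mitochondrial chaperones and proteases (11 of 15, 12 higher and 1 lower adjusted over the list alone), fatty acid oxidation (10 of 19) and cytosolic tRNA synthetases (16 of 20, 17 adjusted over the list alone, with Wars, 0.83, and Gars, 0.52). Chaperones and stress genes of the endoplasmic reticulum (18 of 22, with Hspa5, 0.48) were higher too. ATF4-linked amino acid genes (13 against 5 of 25, 16 and 6 adjusted over the list alone, with Aldh1l2, 0.94), S phase genes (17 against 1 of 26, 18 and 1 adjusted over the list alone), autophagy and lysosome genes (15 against 2 of 28, 16 and 2 adjusted over the list alone) and alveolar type 2 genes (8 against 2 of 16, 9 and 2 adjusted over the list alone) were also higher. Interferon genes were higher in 19 and lower in 1 of 26 (21 and 1 adjusted over the list alone), with Xaf1 (1.40) and Ifit3 (1.30) up and Stat2 (-0.91) down, since most fell less in A/A cells (adjusted p = 0.321 with an estimated correlation). Lower were glycolysis and hypoxia genes (20 against 1 higher of 28, 21 and 1 adjusted over the list alone, with Slc16a3, -1.88, and Egln3, -1.76), cholesterol synthesis (17 of 25, 18 adjusted over the list alone), fatty acid synthesis (9 of 15, 12 lower and 1 higher adjusted over the list alone), transitional alveolar genes (18 against 3 of 24, 19 and 3 adjusted over the list alone, with Slc4a11, -2.11), p53 targets (11 against 1 of 18, 12 and 1 adjusted over the list alone, with Perp, -1.16), mesenchymal genes (11 against 1 of 21, 11 and 2 adjusted over the list alone) and NRF2 targets (10 against 3 of 22, 11 and 3 adjusted over the list alone, with Nqo1, -2.04). Median and mean differed in sign for gut endoderm genes (-0.15 and 0.29), neuroendocrine (0.00 and -0.18), endothelial (0.08 and -0.03) and leukocyte markers (0.18 and -0.01). The test pointed against the median for alveolar type 1 genes (0.12, lower), airway genes (-0.19, higher), NF-kB targets (0.01, lower), fibroblast markers (0.24, lower) and mRNAs of mitochondrial DNA (-0.00, higher). None of these lists was called.

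**Figure D3:**
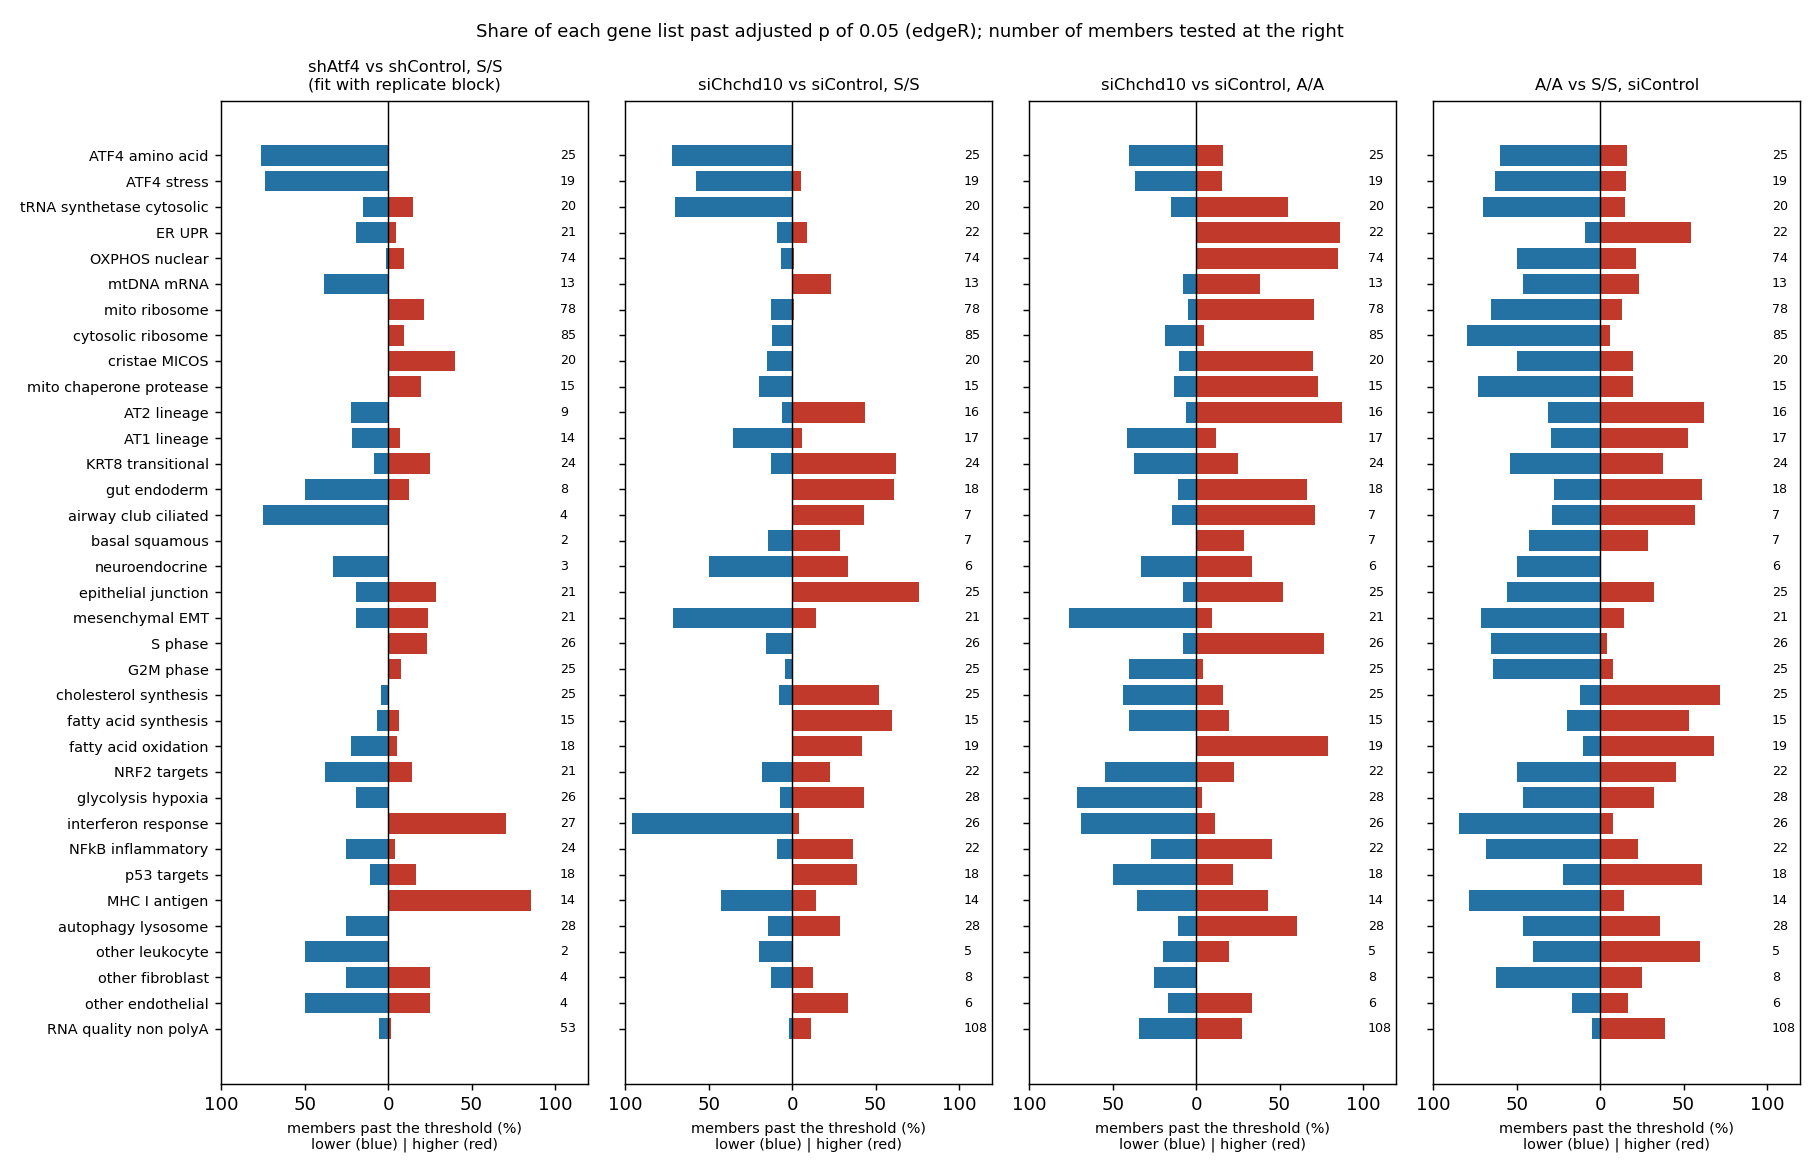
Share of the tested members of each gene list that were lower (blue) or higher (red) at an adjusted p under 0.05, in percent, with the number tested at the right; shAtf4 is shown from the fit with the replicate block. Of 74 respiratory chain genes, 63 rose and none fell with siChchd10 in A/A cells, while 1 rose and 5 fell in S/S cells.

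A/A against S/S cells, both with siControl, asks how cells that cannot phosphorylate eIF2α differ without knockdown. They differed in 12741 of 18138 genes (70.2%), 6453 higher and 6288 lower in A/A cells, and 3913 by at least 2-fold. Against a minimum fold of 1.5, 4604 passed. The labels do not say how many tumours the cells of each genotype came from, so differences between the cell populations cannot be told apart from the effect of the site. The transporter gene Slco4c1, the clock factor gene Npas2, the carboxylesterase genes Ces1d and Ces1c, and Allc had no count in any S/S siControl library, and were at least 79.3-fold, 43.0-fold, 31.9-fold, 24.4-fold and 26.4-fold higher in A/A cells. The amino acid transport partner Cltrn measured 35.2 ± 2.24 against 0.0621 CPM, a ratio of 576 (counting interval 329 to 1115). The complement regulator gene Cd55 (7.70, 70.9 against 0.353 CPM), Tm4sf20 (7.56) and Shisa6, with 1791 against 10 counts, a ratio of 176 (95.6 to 368), were also higher. Serpine2 (-5.94, 0.741 against 47.9 CPM), the splicing regulator gene Esrp1, the small heat shock gene Hspb8 (-5.99), Pax3 (-5.81), Tnik (-6.40), Ildr2 (-6.02), Slc9a2 (-5.80), Sntb1 (-5.75) and Prune2 (-5.73) were among the largest falls. Each of these 9 was highest, within A/A siControl, in replicate 1, and these folds rest largely on that library. Esrp1 had all of its 11 A/A counts there against 690 in S/S cells, so no ratio is given; Serpine2 measured 2.63, 0.336, 0 and 0 CPM in replicates 1 to 4. Without replicate 1 all 9 calls stayed, and the differences were larger, for example -7.54 for Prune2 and -7.12 for Sntb1. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d rose by 1.37 to 1.67.

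Camera called 16 of 35 lists in A/A against S/S cells, none with an estimated correlation. The adjusted p-values were then 0.594 for interferon genes, mesenchymal genes and non-polyadenylated RNAs and 0.706 for the other 13. Cytosolic ribosomal proteins fell in 68 and rose in 5 of 85 (68 and 6 adjusted over the list alone), with Rpl39 (-0.88) and Rpl36a (-0.78; median -0.31, camera adjusted p = 2.41e-06, adjusted p = 0.706 with an estimated correlation), and mitochondrial ribosomal proteins fell in 51 and rose in 10 of 78 (52 and 10 adjusted over the list alone), with Mrpl15 (-0.97). ATF4-linked amino acid genes fell in 15 and rose in 4 of 25, with Bcat1 (-2.20, 49.4 to 10.7 CPM) and Cth (-1.59, 87.6 to 29.0 CPM), and ATF4-linked stress genes fell in 12 and rose in 3 of 19, with the hormone gene Fgf21 (-3.73) and Atf3 (-2.11) down and Gdf15 (0.94) up. Cytosolic tRNA synthetases fell in 14 and rose in 3 of 20, with Gars (-0.80). Interferon genes fell in 22 and rose in 2 of 26, with Rsad2 (-2.03) and Ifit2 (0.57; camera adjusted p = 0.000266, adjusted p = 0.594 with an estimated correlation), and MHC class I genes fell in 11 and rose in 2 of 14. NF-kB targets fell in 15 and rose in 5 of 22, with Ccl2 (-4.74) and Csf3 (1.99). Mesenchymal genes fell in 15 and rose in 3 of 21, with Snai2 (-2.69) and Prrx1 (-2.21). S phase genes fell in 17 and rose in 1 of 26, G2/M genes fell in 16 and rose in 2 of 25, and mitochondrial chaperones and proteases fell in 11, with Lonp1 (-1.10), and rose in 3 of 15. Cholesterol synthesis rose in 18 and fell in 3 of 25 (18 and 4 adjusted over the list alone), with Tm7sf2 (1.02), and fatty acid oxidation rose in 13 and fell in 2 of 19, with Acaa2 (1.63) and Decr1 (-2.57). Gut endoderm genes rose in 11 and fell in 5 of 18, with transthyretin (Ttr, 7.23) and Cym (389 against 10 counts, a ratio of 38.3) up and the intestinal factor gene Cdx2 (-4.40) down (camera adjusted p = 0.0477, adjusted p = 0.706 with an estimated correlation). Alveolar type 2 genes, not called (camera adjusted p = 0.0574), rose in 10 and fell in 5 of 16, with Sftpb (6.83, 2.59 to 290 CPM) and Dram1 (2.81), and Nkx2-1, which drives lung identity, rose from 37.4 to 115 CPM. Alveolar type 1 genes rose in 9, with Ager (2.12), and fell in 5 of 17, and airway genes rose in 4, with Muc5b (3.32), and fell in 2 of 7, with Foxj1 (-5.07). Epithelial junction genes fell in 14, with Marveld2 (-5.46), and rose in 8, with Tjp3 (1.59), of 25. The respiratory chain list fell in 37 and rose in 16 of 74, with Ndufa1 (-0.69) and Atp5a1 (0.66), the mRNAs of mitochondrial DNA fell in 6 and rose in 3 of 13, with ND3 (-4.12), and cristae genes fell in 10, with Phb2 (-0.67), and rose in 4 of 20. Basal markers (3 fell, 2 rose of 7) and neuroendocrine markers (3 fell of 6, with Insm1, -1.51) were not called. Non-polyadenylated RNAs rose in 42 and fell in 5 of 108 (40 and 4 adjusted over the list alone), with H4c8 (1.84), a group that library preparation can move. Fibroblast markers fell in 5 and rose in 2 of 8, leukocyte markers rose in 3 and fell in 2 of 5, and endothelial markers rose in 1 and fell in 1 of 6, none of them called. Ranking by the edgeR statistic ended the calls of mitochondrial chaperones and proteases, cholesterol synthesis and NF-kB targets (adjusted p = 0.0568 each), MHC class I genes (0.0626), G2/M genes (0.181) and non-polyadenylated RNAs (0.228), and the stricter filter that of gut endoderm genes (0.0572). NRF2 targets had a median of -0.08 and a mean of 0.09, leukocyte markers 0.64 and -0.26, and endothelial markers 0.13 and -0.20.

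Effects were compared across genes between comparisons that share no control library; genes are not independent replicates, so no p-value is given for the correlations or the shared counts. The S/S control cells of the shRNA and siRNA tables differed in lineage genes, for example Nkx2-1 at 0 CPM in shControl and 37.4 CPM in siControl. A lack of agreement between shAtf4 and the siRNA comparisons therefore cannot be told apart from this difference between the cells. Over 14180 genes tested in both, fold changes of shAtf4 and of siChchd10 in S/S cells correlated at r = -0.108 (Spearman -0.139). They shared 4 genes higher, where 3.04 are expected from independent lists, and 12 lower, where 7.66 are expected, while 7 rose with shAtf4 and fell with siChchd10 and 10 did the reverse. With the replicate block 150 were shared higher against 207 expected and 278 lower against 206, and more genes went in opposite directions: 341 rose with shAtf4 and fell with siChchd10, and 385 did the reverse. For shAtf4 and A/A against S/S the correlation was -0.0153 (Spearman -0.122), with 6 shared higher against 7.18 expected and 21 lower against 18.9, and 13 and 24 in opposite directions. With the block 391 were shared higher against 519 expected and 576 lower against 542, while 782 rose with shAtf4 and were lower in A/A cells and 634 did the reverse. The siChchd10 effects in S/S and A/A cells correlated at 0.355 (Spearman 0.344), with 1475 genes shared higher against 721 expected and 1330 lower against 642, and 396 and 270 in opposite directions.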

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

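The tests of the RNAs of S/S type in A/A siControl replicate 1 and 3 of the 4 tests of the Y-linked genes (all but depth) were chosen only after the result was seen. Of 230 sets of 4 values of named genes, 22 (9.57%) had a library whose gap to the nearest of the others took up most of the range, where chance picks about 1 in 20, and A/A siControl replicate 1 was that library in 6. The same held in 6 of 54 sets of other values. S/S shAtf4 replicate 4 had a ribosomal protein share of 4.53%, S/S siControl replicate 3 a ribosomal protein share of 4.85% and 4.91% of counts in its 10 most abundant genes, and S/S siChchd10 replicate 4 an rRNA share of 0.513%. Eif2s1 stood apart in replicate 4 of both shRNA groups, at 275 CPM in shControl and 295 CPM in shAtf4. Other results drew attention because the siChchd10 effect differed between the genotypes by the interaction test. They were the 6461 genes past the threshold, the 666 among them that changed in opposite directions, Chchd10 (0.49, adjusted p = 0.0205) and Eif2s1 (0.29, adjusted p = 0.000650), which did not pass in S/S cells (-0.11) and rose in A/A cells (0.18).

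Other splits of the libraries were counted for each comparison. For siChchd10 in S/S cells, siChchd10 in A/A cells and A/A against S/S, only the real split gave as many genes. At 1 of 35, the smallest share possible, this argues only against an arbitrary grouping of these libraries. The labels do not say whether the libraries came from separate cultures, so chance differences between cultures are not excluded. For shAtf4 the real split gave 79 genes and the highest other 0, with 1 of 35 splits giving as many, in the fit without the block. The replicate numbers were taken to pair these libraries, which the data do not settle. If they do, only 8 splits part all 4 pairs, too few for a share under 0.05. The other 7 gave 0, and the rest of the 35 mix the pairs. For siChchd10 the real split gave 5076 and the highest other 450 in S/S cells and 9748 and 0 in A/A cells, and for A/A against S/S 12741 and 0, each 1 of 35. The 450 came from S/S siControl 1 and 4 with S/S siChchd10 3 and 4. For the interaction 1 of 100 splits gave 6461 genes, and the highest other gave 4625, but this count does not decide on chance. Splits within a genotype put the siRNA effect itself, large in both genotypes, into the spread: the 92 that mixed both genotypes gave 0 genes, and the 7 that kept 1 genotype whole gave 322 to 4625.

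RNAs of S/S type stood in A/A siControl replicate 1 at a median of 6.47% of their S/S level over 7 genes, Serpine2 among them, and at 6.72% over a wider set of 37 genes also chosen after the values were seen. Greater depth is argued against, since the library held 1.07 times the median total of the other A/A siControl libraries. Separate activation of the genes is argued against as well, since 100% of the 7 lay within 2-fold of the median share. A candidate explanation is RNA or cells of the S/S culture in that library, because the shares lay close together (75th over 25th percentile 1.19), and a mixture in culture and one in the tube were not separated. Without replicates 1 and 2 the lower calls among the 7 genes went from 6 to 0 for siChchd10 in A/A cells and from 4 to 0 for the interaction, and stayed at 7 for A/A against S/S. Over all genes, 8317 then passed for siChchd10 in A/A cells, 5609 for the interaction and 11899 for A/A against S/S. The main fits, with more libraries, gave 9748, 6461 and 12741. The gene lists were not tested without these libraries.

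The 4 protein-coding Y-linked genes tested lay within 0.389 Mb and kept at most 3.02% of their shControl level after shAtf4 (Eif2s3y). Lower depth is argued against, since the median gene at its shControl level would have given 293 counts in the shallowest shAtf4 library. Cells of a female or unrelated source were tested as well. Autosomal genes over 32-fold apart, 3 without and 4 with the block, came to 0.980% and 1.31% of the 306 between A/A and S/S cells (fitted without a block). This argues only against a source as far apart as the A/A and S/S cells. Another clone or a similar tumour is not covered. Xist stayed at or under 0.0349 CPM, which argues only against female cells that express it. The first form of the test asked every Y-annotated gene to fall under 10%, and it came out against loss of the Y chromosome: Mid1-ps1 kept 68.9% and Gm33272 42.6%. The test was then split in 2 after that result, and loss of the segment with the protein-coding genes may explain their fall (3.02%), whereas loss of the whole chromosome cannot be told apart from it (68.9%), because those 2 genes do not follow the other 4 between A/A and S/S cells either (0.33 and -0.57 against 1.37 to 1.67). Whether Atf4 knockdown or a different cell population brought the loss stays open, and this limit holds for the other changes after shAtf4, Chchd10 among them. In the same comparison chromosome 2 had a median of 0.12, with 67.2% of 1172 genes above 0, and the next autosome, chromosome 3, -0.05; gene positions were not shuffled for it.

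Between A/A and S/S cells whole chromosomes were shifted, with medians of 0.41 on chromosome 18, 0.34 on 16, 0.28 on 3 and -0.22 on 15, where shuffled gene positions gave at most 0.112. GC content and gene length are argued against, since the chromosome 18 median kept 92.6% of its size after their trend was removed (0.37 after it). This covers the 88.9% of autosomal genes with both values. Among genes changed under 2-fold 86.5% was kept. A few strongly changed genes can hardly move a median, so that result was close to fixed and decides nothing about them. Different copy number may underlie the shifts, but the test run for it cannot decide. On chromosome 18, 90.8% of runs of 50 neighbouring genes lay on the same side of 0, against 50.9% of random sets. Chromosome 18 was picked for its median and the random sets came from the other autosomes, so this contrast was largely fixed. The runs show only that the shift spans most of the chromosome. The siChchd10 libraries gave the same pattern (r = 0.982). Some of the differences between A/A and S/S cells may therefore follow the cell populations rather than the phosphorylation site, and DNA was not analysed here.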

How the results depend on the processing

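The fits without both shRNA libraries numbered 4, with or without the block, DESeq2 with the block, and the fits without A/A siControl 1 and 2 were chosen after seeing the data. For shAtf4 the count of 79 became 466 with DESeq2, 24 against a minimum fold of 1.5, 2969 with the replicate block, 1726 without both libraries numbered 4, 3753 with the block as well, and 2739 with DESeq2 and the block. Leaving out 1 library gave 13 (S/S shAtf4 2) to 536 (S/S shControl 4). Against a minimum fold of 1.5 the other comparisons gave 381, 1425, 600 and 4604 genes. That setting tests a stricter question; for the other changes the cause was not tested. Atf4 after shAtf4 kept its direction in 19 of 19 alternatives (-1.45 to -1.21) and its call in 11 (adjusted p 1.44e-09 to 0.157). It lost the call against the minimum fold (-1.33, 0.157) and without any single library but S/S shControl 4 (-1.41 to -1.21). Chchd10 after shAtf4 lay between -1.32 and -0.86 and passed in 4 of 19 alternatives: DESeq2 (-1.11, 0.0135), the block (-1.05, 0.00192), the block without both libraries numbered 4 (-0.95, 0.00702) and DESeq2 with the block (-1.02, 1.18e-10), with adjusted p up to 1 in the others. Chchd10 kept its call in all alternatives run for siChchd10 in S/S (17) and A/A cells (18) and for A/A against S/S (18), as did Atf4 in the last (18). Genes shared by shAtf4 and siChchd10 in S/S cells became 31 higher and 46 lower with DESeq2, 150 and 278 with the block, and 7 lower at an average log2 CPM of 1 or more. Those shared with A/A against S/S became 46 and 125, 391 and 576, and 9 lower. Without A/A siControl 1 and 2, 3 genes turned direction in the interaction without passing (1.68, 2.40 for Serpine2 and 1.34 for Tnik, adjusted p 0.394 to 0.589), and Esrp1 for siChchd10 in A/A cells came to 0.00, as it did without replicate 1 alone, since no count is left (-4.96 without replicate 2). In the siRNA table replicate numbers do not pair the libraries (r -0.171 to 0.157), and the block gave 4703, 9431, 6100 and 12561 genes and ended the gut endoderm call in A/A against S/S (adjusted p = 0.0550). The block also ended the call of Sgsm1 for siChchd10 in A/A cells (adjusted p = 0.0535) and 7 of the 20 named interaction calls, all negative differences, Hdx (0.109) and Stk26 (0.0556) among them. Of the 20 named genes of each comparison, 9, 1, 1, 10 and 0 lost the call against the minimum fold, 1, 0, 0, 5 and 0 with limma-voom, 0, 0, 1, 7 and 0 with the block, and 0 in each with DESeq2. A gene that DESeq2 left without an adjusted p was not counted as lost. Of the 13, 20, 16, 19 and 16 list calls of the 5 comparisons, ranking by the edgeR statistic kept 13, 16, 15, 19 and 10, the block 12, 20, 16, 19 and 15, and the stricter filter 13, 18, 16, 19 and 15. Of the 20 named genes of each comparison 7, 19, 19, 12 and 20 kept their call without any single library.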

Other observations

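None of the values below was planned, and no test was run on them. Replicate 4 differed from replicates 1 to 3 in nearly the same way in both shRNA groups: over 14697 genes the differences correlated at 0.789, and 978 genes lay over 2-fold apart in the same direction in both groups, against 16 in opposite directions. Interferon genes were lower by medians of -2.78 in shControl and -2.37 in shAtf4, with 27 of 27 members on the same side. Cholesterol synthesis (-1.45 and -0.95, 25 of 25) and MHC class I genes (-0.93 and -0.84, 14 of 14) were lower as well. Transitional alveolar genes (0.67 and 0.70, 21 of 24) and non-polyadenylated RNAs (0.71 and 0.66, 47 of 53) were higher.

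The S/S control cells of the shRNA and siRNA tables differed in lineage genes and in the tumour suppressor gene Cdkn2a, in values that were scaled separately. Nkx2-1 had no count in any of the 8 shRNA libraries and 37.4 CPM in S/S siControl. Hnf4a measured 3.64 against 231 CPM and Cdkn2a 0.245 against 209 CPM. Of 36720 genes in both tables, 24 had at least 10 CPM in every S/S siControl and at most 0.1 CPM in every S/S shControl library, among them Klhl13 and Alb, and 0 the reverse.

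The lineage genes of the siRNA table did not move as 1 block. Sftpb measured 2.59, 8.14, 290 and 1177 CPM in S/S siControl, S/S siChchd10, A/A siControl and A/A siChchd10, and Cdh1 603, 747, 982 and 1194 CPM. Epcam measured 8.93, 34.8, 1.44 and 2.57 CPM in the same order, and Vim 2015, 1663, 1818 and 1193 CPM.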
